A study of Homo sapiens with 8 samples.

How the data were processed

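RNA was measured in 8 libraries of LNCaP cells, in 4 groups of 2. Per the labels' protocols, cells were transfected with siRNA for 72 h or given CIA1 at 1 µM for 18 h, RNA was taken with Trizol, and libraries were made with a stranded Illumina mRNA kit. STAR 2.4, RSEM 1.2.14 and the hg19 build are named in the submitters' processing notes, which do not give their order or roles; whether the counting used strand is not given in the sources used here. Genes that overlap an antisense partner therefore cannot be separated with certainty.

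For the 4 siRNA libraries the deposited gene tables list 34495 features by symbol, with transcript identifiers of the UCSC known-gene and Ensembl kinds per the file headers and rows. Their expected count column, per the file headers, is the authors' RSEM estimate of reads per gene, not normalized and not always whole (92.1% to 92.3% of values were whole). The deposited TPM column is the authors' length-scaled abundance, scaled to the same sum in each library. The deposited RPK column is a coverage signal equal to the expected count per kilobase of the listed length, not scaled for library size. The effective length in the deposited tables is another RSEM output and served as an offset in 1 alternative. For the 4 DMSO and CIA1 libraries the deposited files used here hold 17 summary values per library, such as the total expected count and the number of features above an RPK signal of 2.999. Gene-level values of DMSO and CIA1 cells were not analysed here. The same summary values were computed from the gene tables of the siRNA libraries.

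The total expected count was 20751303 to 22585786 per siRNA library and 17227016 to 19862487 per DMSO or CIA1 library. The row that names no gene, at most 0.00097% of a library's counts, was left out of totals used for testing. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 3.23 for siNC and 2.97 for siCOUP-TFII, against 46.7 to 55.2 between groups), so no library was treated as a copy of another. Nothing in the labels says that replicates came from separate cultures, so every p-value measures the spread between these samples, which may be technical. The common dispersion of the fit gave a coefficient of variation of 3.26%.

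Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by TMM, and the robust quasi-likelihood F test compared siCOUP-TFII with siNC without a replicate term. Values were adjusted by Benjamini-Hochberg over 14617 genes and called at 0.05. Standard errors (SE) are those of the log2 fold change implied by the F statistic; TPM values are given as mean ± SD over 2 libraries. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 42 of 45 lists that had at least 5 tested members. camera was repeated with an estimated correlation, and fry from the same package tested each list by itself. DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), other scalings, other filters, effective length offsets, a replicate block and leaving out each library in turn were the alternatives. In data simulated from these libraries over 14617 genes, 50 genes were changed at each fold size, drawn from genes above a minimum count. The simulated dispersion was the one fitted to these same libraries. The edgeR test of siCOUP-TFII against siNC recovered 62% of genes changed by 1.2-fold, 72% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. It called 0.09% of unchanged genes, a rate that does not carry over to the real data, where 56.5% of genes were called.

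The groups, tests, alternatives, gene lists and the rule for naming genes were set before the data were examined. Named were NR2F2; the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM whose groups did not overlap; the 10 smallest p-values not already named; up to 4 members with the smallest p in each list described; and 16 fixed genes. Small RNAs, pseudogenes and unnamed loci were passed over. So were 2 features that carry only a sequence accession as their name, a reading of the rule made after their values were seen. Of 1510 list entries, 1494 were matched to the tables by symbol or older symbol. None of the 13 mitochondrially encoded transcripts was matched by name, so that list has no result. Entries in several lists count in each.

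Summary values of CIA1 and DMSO were compared with an exact 2-sided permutation test, in which 2 libraries against 2 cannot give a p below 0.333. For sequence checks, the longest annotated transcript and 3' UTR of each gene were taken from GENCODE release 29 on GRCh38 by symbol, with no coordinates, since the counts were made on hg19; 99.7% of the 12254 tested protein-coding genes had a transcript and 97.2% had a 3' UTR of at least 100 bases. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.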

Results

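The experiments addressed which genes COUP-TFII controls in LNCaP cells, an established prostate cancer line that responds to androgen. COUP-TFII is an orphan nuclear receptor encoded by NR2F2. In 1 experiment, cells received a negative control siRNA (siNC, 2 libraries) or an siRNA against COUP-TFII (siCOUP-TFII, 2 libraries) for 72 h. In the other, cells received the vehicle DMSO (2 libraries) or CIA1, an inhibitor of COUP-TFII, at 1 µM (2 libraries) for 18 h. Total expected counts were 22160591 and 20751303 in the siNC libraries, 21191884 and 22585786 in the siCOUP-TFII libraries, 17227016 and 17893241 in the DMSO libraries, and 17268172 and 19862487 in the CIA1 libraries.

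NR2F2, the target of the siRNA, was 6.91-fold lower in siCOUP-TFII cells than in siNC cells. Its count was 1034 in each siNC library and 154 and 163 in the siCOUP-TFII libraries, and its level was 21.8 ± 1.17 TPM against 3.22 ± 0.113 TPM (SD, n = 2 each). The log2 fold change was -2.79 ± 0.09 (SE), with an adjusted p of 5.25e-17 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The related receptor NR2F6 had a log2 fold change of -0.05 ± 0.06 and an edgeR adjusted p of 0.548. NR2F1, the closest paralog, had counts of 2, 3, 7 and 1 in the 4 libraries and was too low to test.

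Of 14617 genes tested, 4120 rose and 4139 fell in siCOUP-TFII cells, 56.5% in all, by the edgeR test at an adjusted p under 0.05. Most of these changes were small: 66.8% of the called genes differed by less than 1.5-fold, and 505 rose and 620 fell by 2-fold or more. DESeq2 called 5683 of 14383 genes, 2580 of them higher, and kept 68.4% of the genes called by edgeR. A test against a 1.5-fold change called 492 higher and 752 lower genes. With limma on log2(TPM + 1), 61.7% of the called genes were higher, against 49.9% in the edgeR test. The median gene lay 0.10 higher on the log2 scale in that setting. Its test and gene filter also differed, with 13420 genes tested. Without the filter, at 20855 genes, 61.4% of the called genes were higher and the shift was 0.0981. These values argue against the filter as the cause of either difference. The parts of the TPM scale and of the test in the share of higher genes were not separated. The feature RNA5-8S5, a ribosomal RNA gene, took 2.17% and 2.72% of counts in the siCOUP-TFII libraries and 2.07% and 1.72% in the siNC libraries.

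**Figure D1:**
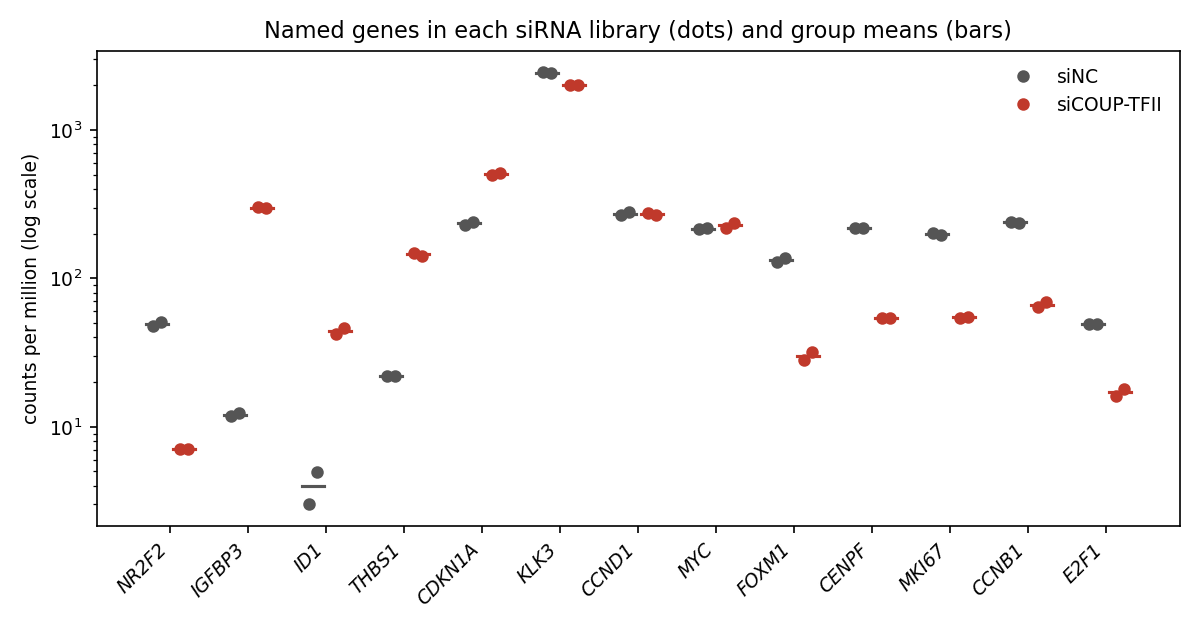
CPM on a log axis for 13 named genes in each siRNA library, with dots for the libraries and bars for the mean of each group of 2. NR2F2, FOXM1, CENPF, MKI67, CCNB1 and E2F1 lie lower in both siCOUP-TFII libraries, IGFBP3, ID1, THBS1 and CDKN1A lie higher, and CCND1 overlaps between groups.

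Genes of mitosis fell together in siCOUP-TFII cells. All 78 tested members of the mitosis and G2/M list fell, with a median log2 fold change of -1.85, and the count adjusted over the list alone was also 78. CENPF, a kinetochore protein, went from 34.8 ± 0.707 to 9.25 ± 0.113 TPM (SD, n = 2 each), a log2 fold change of -2.02 ± 0.04. NUSAP1, which bundles spindle microtubules, fell by 2.09 ± 0.05 on the log2 scale, the proliferation marker MKI67 by 1.86 ± 0.04 and cyclin B1 (CCNB1) by 1.84 ± 0.04, each with an edgeR adjusted p of 7.2e-19 (Benjamini-Hochberg). FOXM1, a transcription factor that drives mitotic genes, was 4.41-fold lower. The list had a camera adjusted p of 1.8e-33 with the preset correlation, and an adjusted p = 0.408 with an estimated correlation. Other genes named for their small p-values were CDK1 (3.23-fold lower), the cytokinesis protein PRC1 (4.43-fold), the kinetochore protein ZWINT (3.71-fold), the chromatin protein HMGB2 (3.80-fold), the nuclear import receptor KPNA2 (2.62-fold) and the zinc transporter SLC39A6 (2.50-fold).

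DNA synthesis genes fell as well. Of 53 tested members of the replication and S phase list, 51 fell and 0 rose over all genes, and 52 fell when adjusted over the list alone. RRM1, a subunit of ribonucleotide reductase, was 2.69-fold lower, the flap endonuclease FEN1 2.87-fold, the ATPase ATAD2 2.56-fold and the replicative helicase subunit MCM7 2.35-fold. E2F1, which activates S phase genes, went from 31.1 ± 0.523 to 11.7 ± 0.806 TPM (SD, n = 2 each). The camera adjusted p was 5.5e-21 with the preset correlation, and the adjusted p = 0.289 with an estimated correlation. Among 39 tested DNA repair genes, 32 fell and 5 rose, counts that did not move when adjusted over the list alone. The Fanconi genes FANCI and FANCD2 were 3.59-fold and 3.43-fold lower, RAD54L was 3.94-fold lower and PARP1 was 1.63-fold lower. The repair list had a camera adjusted p of 1.27e-08, and an adjusted p = 0.408 with an estimated correlation.

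**Figure D2:**
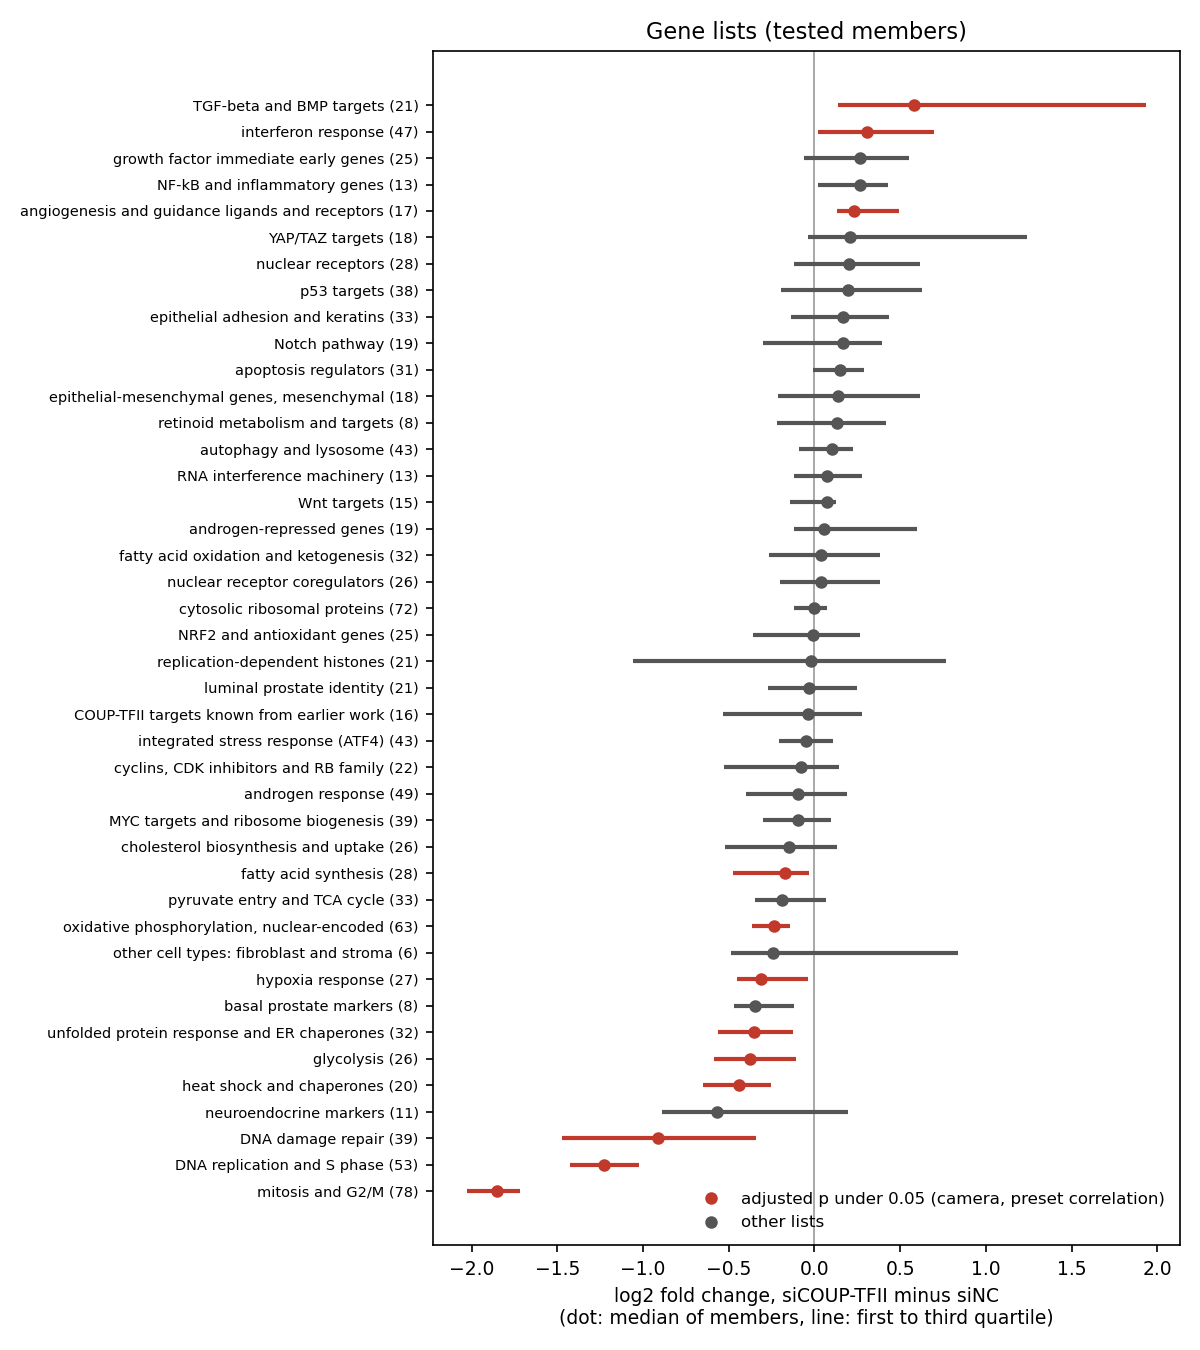
Log2 fold change, siCOUP-TFII minus siNC, of the 42 tested gene lists, with the number of tested members in parentheses. Dots mark the median of the members and lines run from the first to the third quartile, and red marks an adjusted p under 0.05 by camera with the preset correlation. Mitosis lies lowest at -1.85, and the TGF-beta and BMP list lies highest at 0.58.

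Cyclins and their inhibitors moved in both directions. The cyclin-dependent kinase inhibitor CDKN1A (p21) rose from 192.5 ± 8.16 to 437 ± 7.65 TPM (SD, n = 2 each), and the retinoblastoma relative RBL2 rose 1.54-fold. CDK2 was 1.91-fold lower and SKP2, which targets cell cycle inhibitors for degradation, was 2.08-fold lower. Cyclin D1 (CCND1) had a log2 fold change of -0.01 ± 0.03 with an edgeR adjusted p of 0.778. In this list of 22 tested genes 5 rose and 10 fell, the same counts when adjusted over the list alone, and the camera adjusted p was 0.384. Among 38 tested p53 targets, 18 rose and 11 fell (18 and 12 when adjusted over the list alone). BTG2 rose 2.17-fold and RRM2B 1.88-fold, while MDM2, the p53 ubiquitin ligase, fell 1.75-fold. The camera adjusted p of the p53 list was 0.113. MYC had a log2 fold change of 0.07 ± 0.04 with an edgeR adjusted p of 0.141; without siCOUP-TFII replicate 1 the log2 fold change was 0.14 and the edgeR adjusted p 0.0294, and it also passed the edgeR test with total library size (0.13, adjusted p 0.014) and on the TPM scale (0.19, adjusted p 0.0169 by limma).

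The largest falls by the naming rule included several genes outside those lists. Among genes with a mean of at least 5 CPM, DHRS2, a short-chain dehydrogenase, fell most, 9.25-fold, from 35.8 ± 0.502 to 4.04 ± 0.276 TPM (SD, n = 2 each). After NR2F2 came the histone chaperone ANP32E (5.80-fold lower), PTTG1 (securin, 5.47-fold), FAM72A (5.28-fold), TROAP (5.23-fold), the formin DIAPH3 (4.91-fold), the meiotic gene MND1 (4.86-fold), the helicase PIF1 (4.83-fold), the mitotic activator CDC20 (4.81-fold), the centromere protein CENPW (4.75-fold) and FAM72D (4.71-fold). FAM72A and FAM72D are near-identical copies, so the split of reads between them is uncertain. All 12 genes of largest fall had an edgeR adjusted p of 1.44e-10 or less (Benjamini-Hochberg). Among all named genes, the longest annotated 3' UTRs of 7 held both heptamers GATATAT and GCAATTC, which also occur in NR2F2 transcripts. Of these, ANP32E, SLC39A6, MSMO1, CANX, MDM2 and HDAC2 fell, and DSC2 rose 2.13-fold. Both heptamers were picked by their scores in these same fold changes, given below, and most genes were named for their change. The falls of these carriers are therefore no independent evidence about the heptamers.

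Among genes with a mean of at least 5 CPM, IGFBP3, a secreted binder of insulin-like growth factors, rose most, 24.8-fold, from 9.63 ± 0.551 to 257 ± 3.25 TPM (SD, n = 2 each). The inhibitors of differentiation ID1, ID3 and ID2, known targets of BMP signalling, rose 11.1-fold, 6.30-fold and 4.39-fold. Thrombospondin 1 (THBS1), an inhibitor of angiogenesis, rose 6.57-fold. Also among the largest rises were the adrenergic receptor ADRA2A (7.86-fold), endothelial nitric oxide synthase NOS3 (6.96-fold), RAB43 (4.76-fold), JUNB (4.26-fold), the interferon-inducible GTPase GBP2 (4.04-fold), the cytokine TNFSF15 (3.97-fold) and the sulfate transporter SLC26A1 (3.96-fold). RAB43, which overlaps a read-through transcript, had counts of 26 and 53 against 157 and 245 and an edgeR adjusted p of 0.00211, the largest of the 12. The IGFBP3 rise had an edgeR adjusted p of 1.42e-24.

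Targets of TGF-beta and BMP signalling rose as a list. Of 21 tested members, 15 rose and 1 fell (16 and 1 when adjusted over the list alone), with a median log2 fold change of 0.58. ID3, ID2, ID1 and KLF10 had the smallest p-values, and KLF10 rose 1.49-fold. SMAD7, an inhibitor of the pathway, rose 1.72-fold, from 5.90 ± 0.226 to 10.8 ± 0.262 TPM (SD, n = 2 each). The list had a camera adjusted p of 5.99e-04, and an adjusted p = 0.408 with an estimated correlation. Ligands and receptors of angiogenesis and guidance also rose: 10 of 17 tested members were higher and 0 lower, the same when adjusted over the list alone. Besides THBS1, the neuropilin NRP1 rose 1.41-fold, EFNB2 1.41-fold and SEMA3B 1.85-fold. That list had a camera adjusted p of 0.00875, and an adjusted p = 0.408 with an estimated correlation.

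Genes reported in earlier work as COUP-TFII targets gave a mixed picture. Of 16 tested, 3 rose and 6 fell, the same when adjusted over the list alone, and the camera adjusted p was 0.579. The camera test asks for a shift in 1 direction, and the list was not split by expected direction. That p-value therefore cannot decide whether these genes responded. The share called was 56.2%, against 56.5% of all tested genes. CENPF, FOXM1 and E2F1 fell, at log2 fold changes of -2.02 ± 0.04, -2.14 ± 0.06 and -1.52 ± 0.07, while NRP1 rose at 0.49 ± 0.04. CENPF and FOXM1 are also in the mitosis list, where all 78 tested members fell. E2F1 is also in the replication and S phase list, where 51 of 53 fell. Their falls therefore do not set COUP-TFII targets apart from other cell cycle genes. MPC1, a mitochondrial pyruvate carrier subunit, had a log2 fold change of -0.23 ± 0.08 with an edgeR adjusted p of 0.018. That call was lost without siNC replicate 2 (-0.16, edgeR adjusted p 0.159), without siCOUP-TFII replicate 2 (-0.20, 0.109), with total library size (-0.17, 0.0774), with DESeq2 (-0.24, 0.146) and on the TPM scale. ANGPT1 had 0 counts in all 4 libraries, which allows up to 3 counts in each.

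Genes of the androgen response moved in both directions. FOXA1, a pioneer factor of prostate cells, had a log2 fold change of -0.03 ± 0.03 and an edgeR adjusted p of 0.443. KLK3, which encodes prostate-specific antigen, fell 1.21-fold with an edgeR adjusted p of 9.81e-08. In the androgen response list 15 of 49 tested members rose and 23 fell, also when adjusted over the list alone, and the camera adjusted p was 0.257. ADAMTS1 and the prostatic acid phosphatase ACPP rose 1.95-fold and 1.84-fold, and NCAPD3 and PPAP2A fell 1.77-fold and 1.51-fold. Androgen-repressed genes counted 8 higher and 6 lower of 19 (unchanged when adjusted over the list alone, camera adjusted p 0.344), with IGFBP3, PEG3 (1.67-fold), UGT2B11 (1.75-fold) and QKI (1.57-fold) higher. Of 21 luminal identity genes 9 rose and 9 fell, again in both adjustments, with KLK2 (1.45-fold) and HOXB13 (1.47-fold) lower and KRT8 (1.35-fold) higher; the camera adjusted p was 0.966.

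Oxidative phosphorylation, glycolysis and hypoxia lists were lower, by small amounts. Whether a trend with GC content and transcript length, given below, has a part in these shifts was not tested for these lists. Of 63 tested nuclear-encoded oxidative phosphorylation genes, 50 fell and 1 rose (51 and 1 when adjusted over the list alone), with a median log2 fold change of -0.24. UQCRC2 of complex III was 1.55-fold lower, the ATP synthase subunit ATP5B 1.41-fold, NDUFB10 of complex I 1.46-fold and NDUFB6 2.46-fold. The camera adjusted p was 6.21e-07, and the adjusted p = 0.485 with an estimated correlation. Of 26 glycolysis genes 19 fell and 4 rose (20 and 4 when adjusted over the list alone). The lactate dehydrogenases LDHB and LDHA were 1.79-fold and 1.67-fold lower, PGK1 1.57-fold and ENO1 1.36-fold. That list had a camera adjusted p of 0.00127, and an adjusted p = 0.408 with an estimated correlation. Hypoxia-responsive genes fell in 19 of 27 cases and rose in 4, in both adjustments, with BHLHE40 (1.73-fold), PFKFB4 (1.71-fold) and NDRG1 (1.38-fold) lower and MXI1 (1.44-fold) higher. Its camera adjusted p was 0.00875, and the adjusted p = 0.408 with an estimated correlation. In the list of pyruvate entry and the TCA cycle 20 of 33 fell and 7 rose, in both adjustments, and the camera adjusted p was 0.0743; MDH1 was 1.61-fold lower, MPC2 1.35-fold lower, SUCLG2 1.37-fold higher and OGDH 1.30-fold higher.

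Lipid synthesis genes included falls and rises. Of 28 fatty acid synthesis genes 14 fell and 4 rose, also when adjusted over the list alone. The desaturases SCD and FADS2 were 1.86-fold and 1.93-fold lower, ACSL1 1.64-fold and ELOVL7 1.41-fold. The camera adjusted p was 0.0182, and the adjusted p = 0.408 with an estimated correlation. Of 26 cholesterol genes 15 fell and 7 rose in both adjustments, with a camera adjusted p of 0.104. MSMO1, a sterol oxidase, was 3.81-fold lower, and INSIG1, FDPS and EBP were 1.94-fold, 1.96-fold and 1.98-fold lower.

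Chaperones fell and interferon genes rose. Of 32 endoplasmic reticulum chaperone and unfolded protein response genes 24 fell and 3 rose, in both adjustments, with CANX at 2.27-fold lower, MANF at 2.01-fold, HSP90B1 at 1.53-fold and HSPA5 at 1.47-fold. The list had a camera adjusted p of 1.13e-04, and an adjusted p = 0.408 with an estimated correlation. Of 20 genes in the heat shock and chaperone list 16 fell and 2 rose, in both adjustments, with HSPH1 (2.07-fold), HSP90AA1 (1.95-fold), FKBP4 (1.91-fold) and STIP1 (1.73-fold) lower. Its camera adjusted p was 1.85e-04, and the adjusted p = 0.43 with an estimated correlation. Interferon response genes rose in 25 of 47 cases and fell in 6 (26 and 6 when adjusted over the list alone), led by STAT2 (1.47-fold), DTX3L (1.48-fold), HLA-B (1.72-fold) and GBP1 (4.05-fold). The camera adjusted p was 0.00429, and the adjusted p = 0.408 with an estimated correlation.

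Markers of other cell types were near the floor in most cases. Of 16 fibroblast and stroma markers, 6 could be tested, of which 2 rose and 1 fell in both adjustments, with a camera adjusted p of 0.873. ACTA2 rose 3.50-fold to 36.6 ± 0.771 TPM (SD, n = 2), while COL3A1 was at 0.805 and 1.03 TPM, COL1A1 at 2.17 and 1.62 TPM and SPARC at 0.610 and 0.410 TPM in siNC and siCOUP-TFII cells. The endothelial marker VWF was at 1.71 and 0.970 TPM and the leukocyte marker CD68 at 3.61 and 9.36 TPM, each the only tested member of its list.

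The inhibitor experiment could be compared only through library summaries. More features exceeded an RPK signal of 2.999 in CIA1 cells (15373 and 15686) than in DMSO cells (15060 and 15073), a difference of means of 463. RPK is not scaled for library size, so depth can move this number. CIA1 replicate 2 had the largest total count, 19862487 against 17227016 and 17893241 in the DMSO libraries, while CIA1 replicate 1 had 17268172. RNA5-8S5 took 5.04% and 4.48% of counts in the CIA1 libraries and 4.29% and 2.90% in the DMSO libraries. Both differences had an exact 2-sided permutation p of 0.333, the smallest that 2 libraries against 2 allow. The share of reads counted was 81.7% and 80.4% in CIA1 cells and 81.7% and 81.8% in DMSO cells. In the siRNA experiment, features above the same signal numbered 15551 and 15575 in siCOUP-TFII cells and 15334 and 15325 in siNC cells. Dose, time and depth differ between the experiments. A code in the sample titles also separates CIA1 from DMSO libraries, so a batch and the treatment cannot be told apart.

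**Figure D3:**
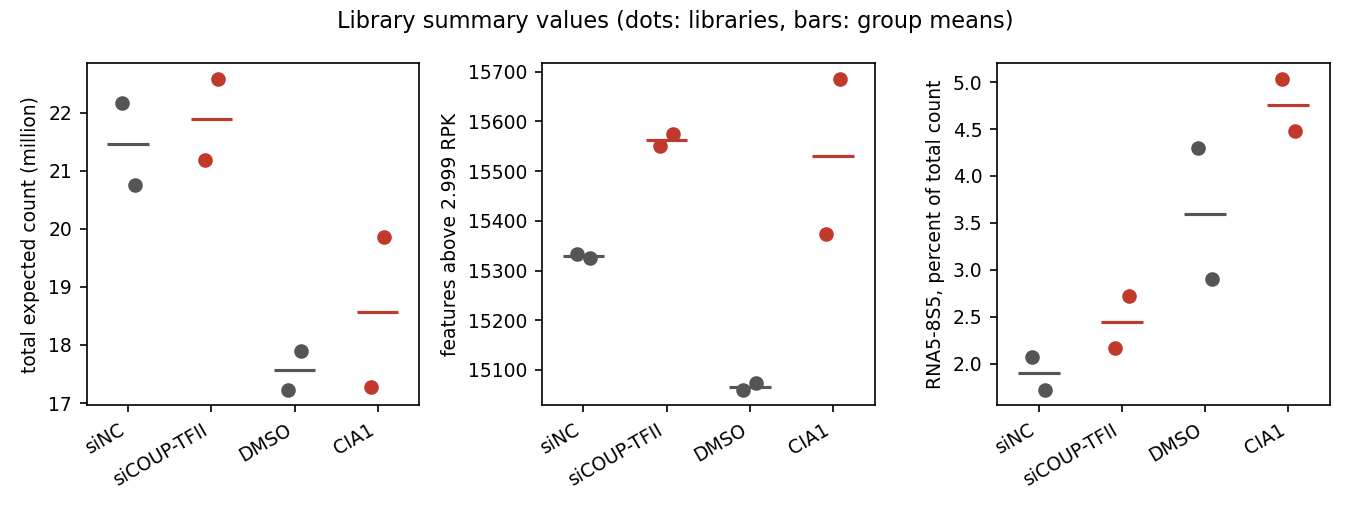
Total expected count, number of features above 2.999 RPK and percent of counts from RNA5-8S5 in each of the 8 libraries (dots) with group means (bars); the vertical axes do not start at 0. Both CIA1 libraries exceed both DMSO libraries in features detected, at 15373 and 15686 against 15060 and 15073.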

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

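NR2F2 kept its fall in every alternative that tested it, and among called genes shared with the edgeR test 0 turned direction under the other scalings, filters and tools on counts, against 5 with effective length offsets and 4 to 6 on the TPM scale. DESeq2 called 2580 genes higher. limma on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) without a filter called 2736, 2729 and 2522 genes lower. A test against 1.5-fold called 492 higher and 752 lower, since it asks for a larger change. Of 42 lists, 12 were called by camera, 0 with an estimated correlation (estimated from 2 residual degrees of freedom) and 35 by fry, which tests each list by itself. TNRC6B, -0.63 on the log2 scale in the edgeR test, was at 0.0491, 0.0539 and 0.0491 in the same 3 TPM settings; the cause was not tested. fry gave the opposite direction to camera for replication-dependent histones (adjusted p 0.0489) and for fibroblast and stroma genes (adjusted p 0.0179), also for a cause not tested. Leaving out each library in turn called 6828 to 8019 genes, with the single library of a group assumed to vary like the other group. The replicate numbers do not pair the samples by any label, and with 2 pairs the correlation of deviations, 0.111, decides nothing; with a replicate block 8425 genes were called, and 99.2% of the genes called without it were kept. Depth left NR2F1, with counts of 1 to 7, and ANGPT1, with none, untested.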

Other observations

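Single genes changed with siCOUP-TFII in further lists, none of which passed camera as a whole. Epithelial adhesion genes counted 18 higher and 9 lower of 33, with E-cadherin (CDH1) 2.01-fold, desmocollin 2 (DSC2) 2.13-fold, KRT8 1.35-fold and ESRP2 1.38-fold higher (camera adjusted p 0.145). Among 31 apoptosis regulators 13 rose and 5 fell: the BH3-only genes PMAIP1 and BMF rose 2.68-fold and 1.64-fold and XIAP 1.92-fold, while BIRC5 (survivin) fell 4.08-fold (camera adjusted p 0.104). Among 43 autophagy and lysosome genes 20 rose and 7 fell, with the cargo receptor SQSTM1 2.26-fold higher and the lysosomal enzymes GUSB and GLA 1.51-fold and 1.65-fold lower (camera adjusted p 0.191). Of 25 antioxidant genes 7 rose (8 adjusted over the list alone) and 10 fell, with HMOX1 2.87-fold and FTL 1.48-fold higher and NQO1 1.66-fold and SRXN1 1.35-fold lower (camera adjusted p 0.776). Immediate early genes counted 10 higher and 2 lower of 25, with FOS 2.94-fold and SPRY4 6.81-fold higher (camera adjusted p 0.0743). Nuclear receptors counted 11 higher and 7 lower of 28; RXRA rose 1.64-fold, NR1D2 1.65-fold and the mineralocorticoid receptor NR3C2 2.21-fold (camera adjusted p 0.22).

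Neuroendocrine markers counted 2 higher and 7 lower of 11, with SYT4 1.73-fold higher and STMN1, EZH2 and ENO2 2.80-fold, 2.12-fold and 1.66-fold lower (camera adjusted p 0.133). Of 32 genes of fatty acid oxidation 12 rose and 8 fell, with the dehydrogenase ACADVL 1.55-fold higher and the hydratase ECHS1 1.49-fold lower (camera adjusted p 0.579). In the integrated stress response list of 43, 9 rose and 18 fell, with PHGDH 2.04-fold and PSAT1 1.27-fold lower (camera adjusted p 0.344). Replication-dependent histones counted 9 higher and 6 lower of 21; the linker histone HIST1H1C fell 2.48-fold, and HIST2H2BE rose 1.36-fold (camera adjusted p 0.966). Cytosolic ribosomal proteins counted 15 higher and 21 lower of 72 with a median log2 fold change of 0.00 (camera adjusted p 0.966). CTGF, a target of both TGF-beta and YAP, had counts of 1 and 0 against 26 and 23 in the siNC and siCOUP-TFII libraries. MYC targets and ribosome biogenesis genes together counted 9 higher and 18 lower of 39, with the polyamine enzyme ODC1 1.47-fold and the nucleolar protein NOP58 1.46-fold lower (camera adjusted p 0.169). Inflammatory NF-kB genes counted 8 higher and 1 lower of 13, with the inhibitor NFKBIA 1.35-fold and the cytokine LIF 1.87-fold higher and CD83 1.68-fold lower (camera adjusted p 0.143). Mesenchymal genes counted 8 higher and 4 lower of 18, with fibronectin FN1 1.30-fold higher (camera adjusted p 0.192), and YAP targets 8 higher and 4 lower of 18, with CYR61 1.76-fold higher and NUAK2 1.70-fold lower (camera adjusted p 0.106). Notch genes counted 7 higher and 5 lower of 19, with HES6 1.81-fold lower (camera adjusted p 0.776), Wnt targets 1 higher and 2 lower of 15, with TNFRSF19 1.32-fold lower (camera adjusted p 0.966), and basal markers 1 higher and 1 lower of 8, with the integrin ITGA6 1.36-fold lower (camera adjusted p 0.344). Receptor coregulators counted 11 higher and 9 lower of 26, with the acetyltransferase EP300 1.56-fold higher (camera adjusted p 0.669), and retinoid genes 3 higher and 2 lower of 8, with RAI1 1.53-fold higher (camera adjusted p 0.569). Of 13 RNA interference genes 5 rose and 2 fell, with AGO1 1.40-fold higher and TNRC6B 1.55-fold and DROSHA 1.28-fold lower (camera adjusted p 0.743); TNRC6B turned direction on the TPM scale (log2 fold change 0.05, limma adjusted p 0.634). Counts adjusted over the list alone were identical in these 2 paragraphs except where given, and every camera value here has the preset correlation.

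Of the tests below, the library scaling test and the splits by the 4 lowest heptamers were chosen after the results were seen, the removal of the GC and length trend after its share of variance was seen, the share of small calls kept after that, and the words "in the members' own 3' UTRs" were added after that result; the others were set before their own results, with the lists' medians already known. In the 3' UTRs of 11911 genes, the 16350 heptamers carried by at least 30 genes were scored for the shift of their carriers, with UTR length, base composition and expression removed. The lowest score was z = -9.91 for GATATAT (1527 genes, median log2 fold change -0.08 against 0.02 in genes without it), then -9.61 for GCAATTC (1093 genes, -0.11 against 0.02), -6.91 for CAATTCA and -6.40 for ACAGGTA, against -4.18 in 1 permutation of the fold changes. GATATAT, GCAATTC and CAATTCA occur in NR2F2 transcripts and ACAGGTA does not, although its reverse complement does. GCAATTC and CAATTCA share the run CAATTC, so their scores and their matches are not independent. Of the heptamers scored, 28.3% occur in NR2F2 transcripts, so 1 match alone says little. This is consistent with the hypothesis that the COUP-TFII siRNA, possibly a pool, also lowered other messages through its seed, although DSC2, which carries all 4, rose 2.13-fold; at least 1 of the 4 occurred in 42.9% of 354 genes lower by 2-fold or more outside the replication, mitosis and repair lists, 28.7% of 338 genes higher by as much and 29.4% of all, shares not independent of the scores that picked the heptamers. The siRNA sequences were not used here and endogenous microRNAs stay open; for the control siRNA the highest score was 5.14, short of the 8 set beforehand, against 4.49 in the permutation.

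The fall of the S phase and mitosis lists was weighed against the same idea. The 113 members whose 3' UTR lacks GATATAT had a median log2 fold change of -1.72 ± 0.05 (bootstrap SD), and the 101 lacking all 4 lowest heptamers -1.70 ± 0.05, which argues against seed pairing in the members' own 3' UTRs. A seed effect on a regulator of these genes, and lower COUP-TFII itself, may each account for the fall and cannot be told apart with 1 siRNA reagent per group.

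The many small changes were weighed last. GC content and transcript length explained 14.2% of the variance among called genes under 1.5-fold. That lay between the 5% and 20% set beforehand, so a part in these changes stays open. Those genes were selected by their fold changes, and over all 12220 genes with sequence the share was 5.95%. The 20% of genes with the highest GC content had a median log2 fold change of 0.14. The medians of 5 equal groups from the shortest to the longest transcripts were -0.12, -0.03, 0.01, 0.05 and 0.12, so shorter transcripts were lower. Among the 12220 genes with sequence, removing that trend from each library gave 5596 called genes under 1.5-fold against 5377 before (1.04 times). Of those 5377, 80.8% were still called in the same direction and the others were lost or turned. These values argue against the trend as the whole cause. After the removal, the median log2 fold change was -1.78 for the mitosis list and -1.08 for the replication list. The other lists were not recomputed, so the trend may have a part in their small shifts. Other scalings moved the number of called genes by at most 1.01 times (1.0062). That total cannot decide whether scaling produces small calls, since a rescaling can trade lower calls for higher ones. With total library size, 92.6% of the main calls were kept, and 57.3% of the called genes were higher against 49.9% in the main test. A biological response and a spread between replicates that is too small because they may be technical cannot be told apart here, since the labels do not say how replicates were made.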
